A study of Rattus norvegicus with 6 samples.

How the data were processed

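Gene expression was measured in synovial tissue from the ankle joints of male rats of 8 weeks with adjuvant arthritis, a model in which Freund's complete adjuvant provokes joint inflammation. Per the labels, 0.1 ml of adjuvant was injected daily for 18 days, and triptolide at 0.4 mg/kg or saline was given daily for 14 days. Per the labels' protocols, 0.5 ug of total RNA was labelled with the dye Cy3 and hybridised to a whole-genome rat oligonucleotide array of 1 colour. The 6 samples form 2 groups of 3 by their titles, arthritis (saline) and triptolide. The labels number the replicates but do not say that they came from separate animals, so the p-values measure the spread between these samples, which may in part be technical. No healthy group was analysed here.

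The deposited scanner files hold spot intensity on a linear scale, with background subtracted and spatial trends removed within each array and nothing normalized between arrays. Per the file headers, they were written by Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. Probe positions are on rat build rn4, per the file headers. A deposited table of the whole series holds log2 values for 167 rows, of which 160 matched a non-control probe. Its columns have medians of 4.94, 5.54 and 4.93 for arthritis 1 to 3 and 4.68, 4.74 and 4.84 for triptolide 1 to 3. Each correlated with the log2 intensity of its own array at r of 0.99985 to 0.99999 across probes, which are not independent replicates, so scale and direction are settled, while the normalization behind the table stays unknown. It was used only as an alternative.

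Each array carries 45018 spots, 43379 of them not controls. The share of non-control spots well above background ranged from 59.6% in triptolide 1 to 65.1% in arthritis 1, the 75th percentile of intensity from 270.1 in triptolide 1 to 447.9 in triptolide 3, and no spot was saturated. With 3 arrays per group, their number limits the precision. Per the file headers, slide 1 (scan 1) held arthritis 1 to 3 and triptolide 1, and slide 2 (scan 2) held triptolide 2 and 3. Slide and group are therefore largely confounded, and values with slide as a block or within slide 1 rest on triptolide 1 alone for the treated side.

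From these files, control spots and outlier-flagged spots were left out, log2 of the processed intensity was taken, each array's log2 75th percentile over non-control spots was subtracted, and spots of the same probe were averaged. Log2 levels in the text are on this scale, so 0 is the array's own 75th percentile. Of 41012 probes, 25772 were well above background on at least 3 of the 6 arrays and were tested. Probe names came from the reference table of rat genes, used for names only: 18028 probes matched by RefSeq accession, 3169 by symbol and 402 by synonym, and 19413 kept the name in the file. In all, 21625 probes carry a settled symbol, for 16436 genes. Where a gene has several probes, the probe with the highest mean signal over all 6 arrays stands for it.

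Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, triptolide minus arthritis, Benjamini-Hochberg adjusted p under 0.05 over all tested probes). A count at 2-fold or more with an unadjusted p under 0.05 is given beside it. Before the data were examined, 42 gene lists (signalling, cell type markers, tissue remodelling, cell state and metabolism) were fixed. Each was tested with limma's camera at a preset correlation of 0.01 between genes, with 1 probe per gene and Benjamini-Hochberg adjustment over the 42 lists. Camera with an estimated correlation, camera on ranks, and fry were run beside it. Fry's directional p tests whether a list moves 1 way on balance and its mixed p whether members move in either direction.

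The rule for named genes was also fixed beforehand and excludes provisional names. It takes the 12 largest differences in each direction among genes past the adjusted threshold whose groups do not overlap, filled up to 12 by the smallest unadjusted p among such non-overlapping genes. It adds up to 4 members of each list with the smallest unadjusted p, and always Tnf, Il1b, Il6, Ptgs2, Mmp3, Mmp13, Vegfa and Ercc3. The rule took 194 genes. Values are given for 65 of them, of which the examples from the lists were picked after their values were seen, and the others are not reported here. The 12 further tested clock genes were named after their values were seen. A gene not well above background on any array of a group is given as "at least N-fold": the mean of the brighter group against the mean of the dimmer group, in which each array takes the higher of the probe's own value and the lowest signal among probes well above background.

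The scripts were tested on simulated data for this comparison with 25772 probes, of which 67, 67 and 66 were set to log2 changes of 1, 2 and 3. With each probe's own measured spread, 13.4%, 62.7% and 80.3% of these were called, with 9 false calls. With the median spread for every probe, 71.6%, 100% and 100% were called, with 8 false calls. In simulated lists, camera and fry directional called the 1 list set to shift out of 42. Fry mixed called both lists set to change and 1 that was not. Genes were drawn independently in this simulation, whereas the estimated correlation within called lists reached 0.87 in the data (MHC class I presentation). The simulated lists therefore do not show how often camera calls falsely here.

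Alternatives covered normalization, background correction (normexp with an offset of 50), the filter on dim probes, outlier spots, probes per gene, the variance model, array weights, slide, a replicate block, leaving out each array and the deposited table. A pair of settings was added after the marker levels had been seen: arthritis 1 and 3 against triptolide 1 and 3, and the skeletal muscle marker mean as a covariate. Replicate numbers were not taken as pairs. Figures were drawn with matplotlib 3.10.9.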

Results

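The effect of triptolide, a diterpenoid of the vine Tripterygium wilfordii, on gene expression in arthritic synovial tissue was examined on 6 arrays, 3 from rats given saline (arthritis) and 3 from rats given triptolide. Between 25850 and 28249 spots per array were well above background.

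By fry's mixed test and by p adjusted over the list alone, though not by camera, the groups separated most clearly in genes of the circadian clock. Dbp, a clock-controlled transcription factor, was higher with triptolide by 1.35 on the log2 scale (SE 0.18), a 2.54-fold difference, with levels of 2.88 ± 0.05 (SD, n = 3) against 1.54 ± 0.25 (SD, n = 3). Bmal1 and Npas2, which encode activators of the clock, were lower, with log2 differences of -1.40 (SE 0.24) and -1.52 (SE 0.28). Bmal1 stood at 1.85 ± 0.33 (SD, n = 3) in arthritis and 0.45 ± 0.29 (SD, n = 3) with triptolide. The probes lie at 96178020 to 96178079 on chromosome 1 for Dbp, 171161969 to 171162028 on chromosome 1 for Bmal1 and 38433884 to 38433943 on chromosome 9 for Npas2 (rn4). Whether each lies in coding sequence or a UTR was not analysed here.

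Of 16 tested clock genes, 8 changed when p was adjusted over the list alone, 4 in each direction, and 0 passed over all probes by limma. Dbp (adjusted p = 0.0033 over the list alone), Per3, Nr1d2 and Nr1d1 rose, and Bmal1 (0.0070), Npas2 (0.0070), Nfil3 and Cry1 fell. Per3, a repressor of the clock, was higher by 0.87 (SE 0.19), and the nuclear receptor genes Nr1d2 and Nr1d1 by 1.00 (SE 0.26) and 0.85 (SE 0.28). Nfil3, a repressor that competes with Dbp for its sites, had a log2 difference of -1.47 (SE 0.38), and the repressor Cry1 one of -0.82 (SE 0.27). With an array left out Cry1 ranged from -0.97 to -0.53. Per1 and Tef, also non-overlapping between groups, differed by 0.46 (SE 0.18) and 0.59 (SE 0.24) without passing the list's adjustment, and Per2 by 0.27 (SE 0.16). The remaining members differed by -0.29 (SE 0.21) for Rora, -0.20 (SE 0.17) for Clock, 0.27 (SE 0.28) for Bhlhe41, 0.075 (SE 0.26) for Bhlhe40 and 5.6e-04 (SE 0.15) for Cry2. Under other scalings Cry2 was below 0 in each, and Clock stood at 0.028 with normexp and quantile normalization. A second, dimmer probe of Npas2 differed by -0.74 (SE 0.32). In all, 10 of the 16 genes had non-overlapping groups, where 10% are expected by chance.

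As a list, the clock genes were apart in either direction by fry's mixed test (adjusted p = 0.0071 over 42 lists). Camera gave them an adjusted p of 0.593, and fry's directional test called 0 of the 42 lists. With slide as a block the difference of Dbp was 1.40, that of Bmal1 -1.48 and that of Npas2 -1.53, but the mixed test gave 0.0789 and 0 members passed over the list alone. Within slide 1 the mixed test gave 0.0186 and 1 member passed. The mixed adjusted p was 0.111 without arthritis 1, 0.0623 without arthritis 3 and 0.0752 without triptolide 1. The number of members past the list's own adjustment was 5 without arthritis 1, arthritis 3 or triptolide 3 and 4 without triptolide 1 or triptolide 2. Of 42 lists, clock genes were the 1 list called by the mixed test.

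**Figure D1:**
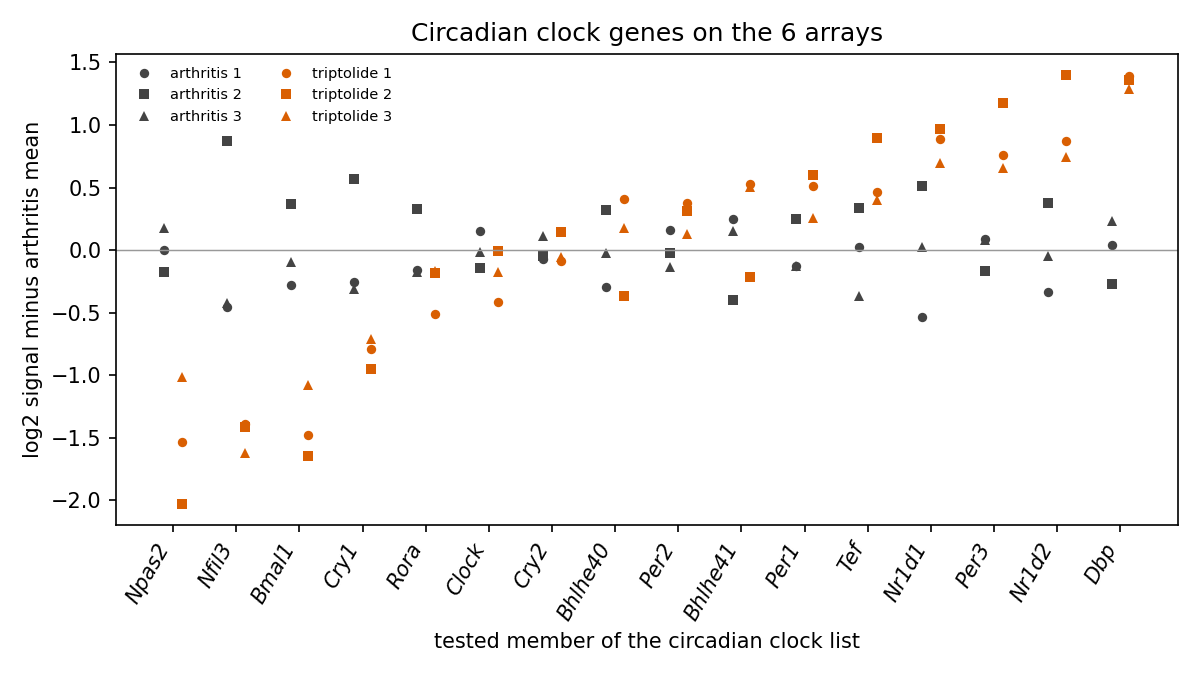
Log2 signal of the 16 tested circadian clock genes on each array, relative to the mean of the 3 arthritis arrays of that gene (vertical axis, log2), with symbols for the replicates and colour for the group. All 3 triptolide arrays lie above all 3 arthritis arrays for Dbp and below them for Bmal1, Npas2 and Nfil3.

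Over all genes, 0 of 25772 tested probes passed an adjusted p under 0.05 by limma, the lowest being 0.344. At an unadjusted p under 0.05 there were 833 probes, where 1289 would be expected by chance, 516 higher and 317 lower with triptolide. This count was 1656 without triptolide 2 and 616 to 948 without any other array. It was 1738 with the muscle covariate and 4343 with array weights. Without arthritis 2, 393 of 861 were higher. Groups did not overlap for 2226 probes, 8.64% of those tested against 10% by chance. A difference of at least 2-fold with an unadjusted p under 0.05 was found for 225 probes, 137 higher and 88 lower, of which 200 were dimmer than the median tested probe. The 2-fold count was 552 with slide as a block and 709 within slide 1. It was 397 without triptolide 1 and 507 without triptolide 2, and normexp background correction left 31 probes, 14 of them higher.

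Outside the clock, the genes named by the smallest unadjusted p among non-overlapping genes had an adjusted p of 0.994 each and are given as values. Among those higher with triptolide, Alppl2, an alkaline phosphatase gene, differed by 1.90 (SE 0.30), Tmem164 by 0.80 (SE 0.14), Sap25 by 1.00 (SE 0.18) and Znf408 by 1.41 (SE 0.28). Pcdhga9, a protocadherin gene, differed by 2.10 (SE 0.37) and Hs3st3a1, a heparan sulfate sulfotransferase gene, by 1.07 (SE 0.21), each well above background on 2 of the 3 arthritis arrays. Wnt6, a secreted Wnt ligand, differed by 2.05 (SE 0.41), was well above background on 1 arthritis array and passed adjusted over the list alone among 23 Wnt signalling genes (adjusted p = 0.0487). Hnf4a, Gsx1 and the olfactory receptor genes Or2aa1 and Or4g17 were not well above background on any arthritis array. They were higher with triptolide by at least 2.71-fold, at least 1.68-fold, at least 1.74-fold and at least 2.25-fold.

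Among genes lower with triptolide, C1qtnf3, which encodes a secreted C1q/TNF-related protein, differed by -1.12 (SE 0.19), and its second probe by -1.24 (SE 0.20). Aspn, which encodes the matrix proteoglycan asporin, differed by -0.79 (SE 0.19), from 2.73 ± 0.19 (SD, n = 3) to 1.94 ± 0.22 (SD, n = 3). The fructose transporter gene Slc2a5 differed by -0.91 (SE 0.21), the hindlimb transcription factor gene Tbx4 by -0.88 (SE 0.19), Nxph1 by -0.91 (SE 0.21) and Lhx2 by -0.93 (SE 0.16). Dnajc5b, Cfap20dc, Reg3a and Tmem79 were not well above background on any triptolide array and were lower there by at least 1.13-fold, 1.45-fold, 1.28-fold and 1.49-fold.

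Of 9 lists of immune signalling and antigen presentation, 4 were shifted upward with triptolide by camera. All 15 MHC class II presentation genes had higher values (mean log2 difference 0.38, adjusted p = 0.011), as did 22 of 23 MHC class I presentation genes (0.41, adjusted p = 3.8e-04), 33 of 37 interferon-stimulated genes (0.42, adjusted p = 0.0044) and 20 of 24 NF-kB pathway genes (0.23, adjusted p = 0.0070). Not called were innate pattern recognition (0.24, adjusted p = 0.0516), chemokines (0.38, 0.0871), inflammatory cytokines (0.25, 0.0871), complement (0.062, 0.603) and eicosanoid enzymes and receptors (0.031, with camera's direction downward, 0.874). Each of the 4 calls was lost with an estimated correlation (adjusted p = 0.939), and 0 members passed adjusted over the list alone. The antigen peptide transporter genes Tap1 and Tap2 differed by 1.00 (SE 0.64) and 1.01 (SE 0.52), the interferon-induced genes Gbp5 and Ifit2 by 1.49 (SE 0.88) and 0.77 (SE 0.38), the MHC class II activator gene Ciita by 0.88 (SE 0.46) and Cd40 by 1.02 (SE 0.63). Without triptolide 1 these 6 values were 0.35, 0.40, 0.58, 0.32, 0.44 and 0.33, and without triptolide 2 Tap1, Gbp5, Ciita and Cd40 were at 1.70, 2.44, 1.34 and 1.62. Nfkbia, the NF-kB inhibitor, differed by 0.63 (SE 0.21) and Ripk1 by 0.37 (SE 0.20), the latter by 0.18 without arthritis 2.

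Neutrophil, macrophage and T and NK cell markers, which camera did not call (mean 0.34, 0.11 and 0.16, adjusted p = 0.0659, 0.570 and 0.603), were lowest on the same 2 arrays as these 4 lists. MHC class II genes stood at -0.56 in arthritis 2 and -0.47 in triptolide 2, neutrophil markers, 14 of 17 of which were higher with triptolide, at -0.48 and -0.46, macrophage markers at -0.52 and -0.62, and T and NK cell markers at -0.73 and -0.78. In triptolide 1 and 3 these stood, in the same order, at 0.57 and 0.46, 0.65 and 0.32, 0.37 and 0.43, and 0.52 and 0.50. The mean of the interferon-stimulated genes lay 1.19 above their mean over all 6 arrays in triptolide 1, 0.15 above it in triptolide 3 and 0.72 below it, at -0.72, in triptolide 2. Without triptolide 1 the mean log2 differences were -0.072 for interferon-stimulated genes, 0.11 for MHC class I, 0.18 for MHC class II and 0.095 for NF-kB (camera adjusted p = 0.388, 0.546, 0.388 and 0.436). Without triptolide 2 they were 0.88, 0.79, 0.70 and 0.40. Without arthritis 2 the calls of MHC class II (mean 0.19, adjusted p = 0.270) and NF-kB (0.099, 0.110) were also lost, without triptolide 3 the same lists (0.24, 0.164 and 0.18, 0.0504), and without arthritis 1 that of interferon-stimulated genes (0.38, 0.0601). With no filter on dim probes the calls of MHC class II (mean 0.42, adjusted p = 0.0634), interferon-stimulated genes (0.41, 0.0634) and NF-kB (0.21, 0.136) were lost. With slide as a block, and equally within slide 1, the means were 1.40 for interferon-stimulated genes, 1.03 for MHC class I, 0.76 for MHC class II and 0.49 for NF-kB.

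Extracellular matrix genes were shifted downward: 30 of 35 had lower values, with a mean log2 difference of -0.28 (camera adjusted p = 2.2e-05; adjusted p = 0.939 with an estimated correlation). Synovial fibroblast markers had 10 of 16 members lower and a mean of -0.22, without a call (adjusted p = 0.189), and were lowest in arthritis 2 and triptolide 2, at -0.46 and -0.52. The matrix genes stood at -0.28, -0.23 and -0.14 in triptolide 1, triptolide 3 and arthritis 2, the 3 arrays highest in muscle markers (1.20, 1.02 and 7.29), and at 0.31, 0.26 and 0.087 in arthritis 1, arthritis 3 and triptolide 2 (-3.49, -3.51 and -2.50). With the muscle marker mean as a covariate the matrix mean was -0.29 (camera adjusted p = 4.3e-05). The groups differed in the muscle mean by -0.19, so this correction could move little and does not exclude tissue makeup. Thbs2, a matricellular glycoprotein gene, differed by -0.89 (SE 0.29), the fibrillar collagen gene Col5a2 by -0.54 (SE 0.21) and the collagen cross-linking enzyme gene Lox by -0.52 (SE 0.20). Timp3, a metalloproteinase inhibitor gene, went the other way by 0.65 (SE 0.19). No member passed adjusted over the list alone. The list's mean was -0.42 with slide as a block and within slide 1. With an array left out it was -0.20 to -0.43, with the camera call kept each time. It was -0.50 with array weights and -0.54 with arthritis 1 and 3 against triptolide 1 and 3. The weighted fit leans on these same arrays, which differ in muscle markers. A second probe of Thbs2 differed by -0.43 (SE 0.23).

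Glucocorticoid response genes were also shifted downward, with 9 of 12 lower and a mean of -0.36 (camera adjusted p = 0.029, and 0.939 with an estimated correlation). The estimated correlation of this list was 0.017, near the preset 0.01, so that loss does not reflect strongly correlated members. Fkbp5, a co-chaperone of the glucocorticoid receptor, differed by -0.92 (SE 0.25) on its brightest probe, -0.89 and -1.03 on the other 2, and Zbtb16 by -1.70 (SE 0.51). Tsc22d3 and Klf9 differed by -0.51 (SE 0.32) and -0.47 (SE 0.30), and by -0.16 and -0.15 without arthritis 2. The list stood at 0.46 in arthritis 2, the array highest in skeletal muscle markers, against 0.078 and 0.0053 in arthritis 1 and 3. It stood at -0.34 in triptolide 2, the array highest in nerve and smooth muscle markers, against -0.051 and -0.15 in triptolide 1 and 3. The mean was -0.23 with slide as a block and within slide 1, where the call was lost (adjusted p = 0.670 and 0.875). It was lost too without arthritis 2 (mean -0.22, adjusted p = 0.178), without triptolide 2 (-0.28, 0.369) and with arthritis 1 and 3 against triptolide 1 and 3 (-0.14, 0.543). Among other settings, it was lost with normexp (-0.22, 0.299), normexp and quantile normalization (-0.23, 0.118), array weights (-0.21, 0.161) and camera on ranks (0.0684). A second probe of Zbtb16 differed by -0.68 (SE 0.45).

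Further lists called by camera were apoptosis (25 of 27 higher, mean 0.16, adjusted p = 0.011), the unfolded protein response (19 of 25 higher, mean 0.12, adjusted p = 0.039), erythroid markers (6 of 7 higher, mean 0.47, adjusted p = 0.035), oxidative phosphorylation (63 of 65 lower, mean -0.24, adjusted p = 5.2e-08), heat shock proteins (19 of 26 lower, mean -0.24, adjusted p = 0.045) and cytosolic ribosomal proteins (50 of 76 lower, mean -0.071, adjusted p = 0.024). These calls too were lost with an estimated correlation (adjusted p = 0.939). Casp9, an apoptosis protease gene, differed by 0.40 (SE 0.18), Atf6 by 0.41 (SE 0.20), the heme synthesis gene Alas2 by 1.07 (SE 0.44), the globin gene Hbb by 0.97 (SE 0.42) and Rps26 by -0.40 (SE 0.16). Derl3, of endoplasmic reticulum degradation, was higher by at least 1.90-fold, being not well above background on any arthritis array. Second probes of Casp9 and Atf6 differed by 0.17 (SE 0.22) and 0.020 (SE 0.16).

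Of these lists, oxidative phosphorylation, heat shock protein and apoptosis genes had means of -0.0064, 0.066 and 0.021 without arthritis 2 (camera adjusted p = 0.867, 0.884 and 0.472). Ribosomal proteins stood at -0.13 without that array, with the call kept. Oxidative phosphorylation and apoptosis stood at -0.14 and 0.29 without triptolide 2, also with the calls kept. Without triptolide 1 the apoptosis (mean 0.048, adjusted p = 0.546), unfolded protein response (0.057, 0.478), erythroid (0.42, 0.153) and heat shock (-0.21, 0.153) calls were lost, and without triptolide 3 those of the unfolded protein response (0.11, 0.0752) and heat shock proteins (-0.19, 0.164). The erythroid call was also lost without arthritis 1 (0.51, 0.126), arthritis 3 (0.20, 0.347) or triptolide 2 (0.40, 0.157), the unfolded protein response call without arthritis 2 (0.060, 0.182) or arthritis 3 (0.13, 0.0580), and the ribosomal call without arthritis 3 (-0.022, 0.309) or triptolide 2 (-0.0036, 0.861). Without arthritis 3 Alas2 and Hbb differed by 0.67 and 0.56, and without arthritis 2 Casp9 by 0.26. With slide as a block, and equally within slide 1, the means were 0.39 for apoptosis, 0.24 for the unfolded protein response, 0.58 for erythroid markers, -0.13 for oxidative phosphorylation, -0.29 for heat shock proteins and 0.036 for ribosomal proteins, the last 4 without a call (adjusted p = 0.0911, 0.0964, 0.203 and 0.596 with the block). Quantile normalization ended the heat shock (-0.22, 0.0925) and ribosomal (0.023, 0.617) calls. Normexp ended the heat shock (-0.16, 0.457), erythroid (0.36, 0.0686) and ribosomal (-0.0046, 0.792) calls, and normexp with quantile normalization these (-0.15, 0.213, then 0.39, 0.0792, then 0.050, 0.104) and the unfolded protein response call (0.093, 0.0792). With no filter on dim probes the apoptosis (0.13, 0.317), unfolded protein response (0.12, 0.317) and erythroid (0.27, 0.215) calls were lost, and with the filter at all 6 arrays that of the unfolded protein response (0.072, 0.104). Array weights ended the calls of apoptosis (0.085, 0.0764), the unfolded protein response (0.088, 0.0700), heat shock (-0.063, 0.241), ribosomal (-0.081, 0.0673) and oxidative phosphorylation genes (0.047, 0.124). The muscle covariate ended the erythroid (0.49, 0.0531), unfolded protein response (0.11, 0.0613) and ribosomal (-0.073, 0.0739) calls. With arthritis 1 and 3 against triptolide 1 and 3 the heat shock (-0.0099, 0.526) and ribosomal (-0.060, 0.480) calls were lost, and oxidative phosphorylation was called upward (0.099, adjusted p = 2.7e-04). Camera called 12 of the 42 lists in all, 7 upward and 5 downward, against 5 without triptolide 1 and 21 without triptolide 2.

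Skeletal muscle markers were highest in arthritis 2, and higher in triptolide 1 and 3 than in the other 3 arrays. All 43 tested markers were highest in arthritis 2, and their mean lay 7.29 above its average over all 6 arrays there, at -3.49 in arthritis 1 and -3.51 in arthritis 3, at 1.20 and 1.02 in triptolide 1 and 3 and at -2.50 in triptolide 2. Pvalb, a calcium-binding protein of fast muscle fibres, differed between groups by -2.53 (SE 2.10), Tnnt3, of fast troponin, by -1.95 (SE 2.04) and Actn3, of the fast fibre Z-disc, by -2.48 (SE 3.06). With an array left out Pvalb ranged from -3.77 to -0.10, Tnnt3 from -3.21 to 0.53 and Actn3 from -4.37 to 1.25. Oxidative phosphorylation and heat shock genes were also highest on that array, with list means of 0.59 and 0.73. Smooth muscle and nerve markers were instead highest in triptolide 2, with means of 1.81 and 2.21, against -0.68 and -0.80 in triptolide 1 and -0.84 and -1.01 in triptolide 3. Array correlations were 0.922 to 0.944 for pairs with arthritis 2 and 0.952 to 0.991 for the others.

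**Figure D2:**
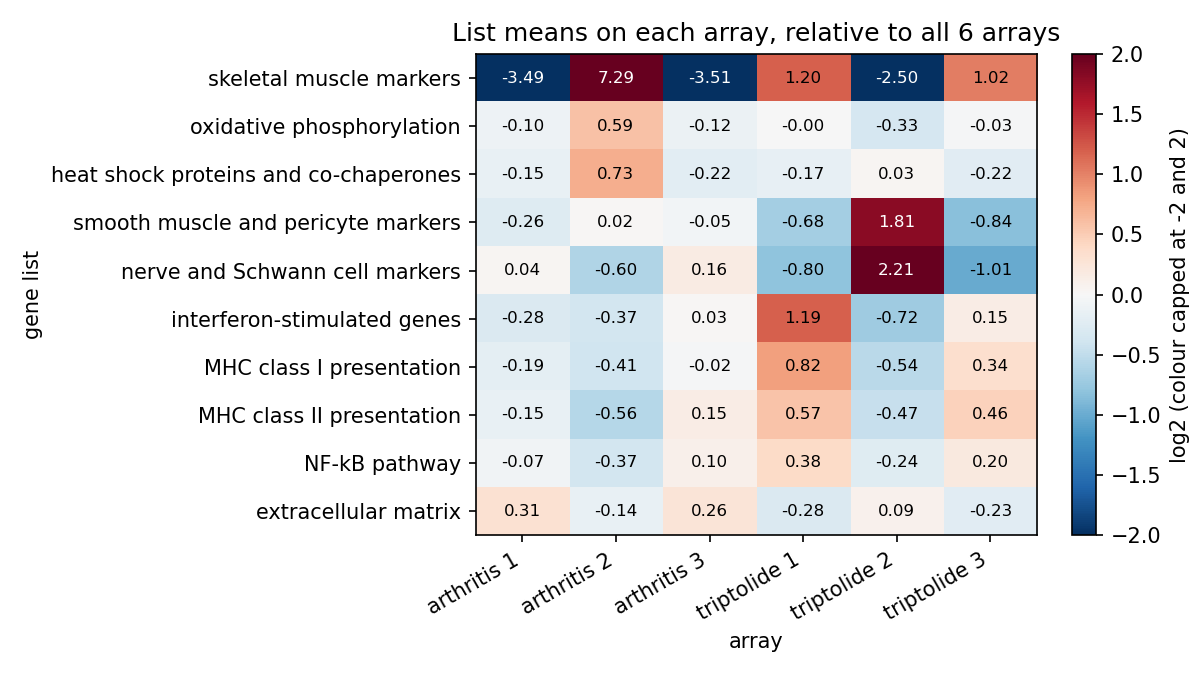
Mean log2 signal of the tested genes of 10 lists on each array, minus the mean of the list over all 6 arrays. Arthritis 2 stands at 7.29 for skeletal muscle markers, triptolide 2 at 2.21 for nerve and Schwann cell markers and triptolide 1 at 1.19 for interferon-stimulated genes.

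Among the inflammatory and joint-destruction genes fixed for reporting, none passed the adjusted threshold by limma (adjusted p = 0.994 each). Vegfa, an angiogenic growth factor gene, differed by 0.71 (SE 0.27), with non-overlapping groups, and a second probe by 0.56 (SE 0.17). The cytokine genes Tnf, Il1b and Il6 differed by 0.55 (SE 0.79), 0.60 (SE 0.54) and 0.23 (SE 0.47). Tnf was well above background on 2 arrays of each group and Il6 on 2 arthritis arrays and 1 triptolide array. The prostaglandin synthase gene Ptgs2 differed by 1.26 (SE 0.63), measured above background on 1 arthritis and 2 triptolide arrays. The metalloproteinase genes Mmp3 and Mmp13 differed by 0.48 (SE 1.00) and -0.31 (SE 0.54). Ercc3, which encodes the transcription factor subunit that triptolide binds, differed by 0.086 (SE 0.18). With slide as a block the differences rest on triptolide 1 alone for the treated side. They were 2.04 for Tnf, 1.31 for Il1b, 1.20 for Il6, 2.40 for Ptgs2, 2.12 for Mmp3, -0.049 for Mmp13 and 0.71 for Vegfa. Without triptolide 1 the differences were -0.20 for Tnf, 0.24 for Il1b, -0.25 for Il6, 0.70 for Ptgs2 and -0.34 for Mmp3. Without an array they ranged from -0.20 to 1.43 for Tnf, 0.24 to 1.12 for Il1b, -0.25 to 0.55 for Il6, -0.34 to 1.39 for Mmp3 and -0.94 to 0.047 for Mmp13, and Vegfa was at 0.47 without triptolide 2.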

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

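Of the 225 probes at 2-fold, 200 lay below the median signal. With the filter at all 6 arrays the lowest adjusted p was 0.993, against 0.344, so leaving out dim probes gave no further calls. The clock tests in each setting, arthritis 1 and 3 against triptolide 1 and 3, and the muscle covariate were chosen after the result was seen, and the others were planned. Unless said, the cause of a difference between settings was not tested.

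The count of 0 probes past the adjusted threshold by limma (833 at an unadjusted p under 0.05) became 1 with array weights, a sequence with no settled name. It became 24 with arthritis 1 and 3 against triptolide 1 and 3, 23 of them higher with triptolide and 13 of them probes of skeletal muscle list genes. In the other settings it was 0. Among settled names outside that list, Dhrs7c, Hjv, Ankrd23, Hspb3, Hhatl and Trim54 differed by 4.14 to 5.87 and Col11a1 by -2.14. In muscle markers, triptolide 1 and 3 stood at 1.20 and 1.02 and arthritis 1 and 3 at -3.49 and -3.51. The 24 calls therefore cannot be told apart from tissue makeup. The same limit holds for the fit with array weights, which leans on these arrays (weights of 0.20 for arthritis 2 and 0.24 for triptolide 2). The 225 probes at 2-fold became 31 with normexp (14 higher), 23 with normexp and quantile normalization (10 higher), 638 with no filter, 92 with the filter at all 6 arrays, 661 with array weights, 552 with slide as a block, 709 within slide 1, 565 with arthritis 1 and 3 against triptolide 1 and 3, and 2 in the deposited table, where 94 probes could be tested. Leaving out an array gave 215 to 507.

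The 12 lists called by camera became 0 with an estimated correlation, 0 by fry directional, 1 by fry mixed, 7 with no filter, 23 with array weights and 24 with arthritis 1 and 3 against triptolide 1 and 3. Leaving out an array gave 5 to 21. The deposited table held too few genes for a list test. List members past the threshold went from 0 to 9 adjusted over the list alone and to 11 with arthritis 1 and 3 against triptolide 1 and 3, of which 10 were skeletal muscle markers. The 8 clock genes past the list's own adjustment became 0 with slide as a block, 1 within slide 1 and 4 to 10 without an array. The mixed adjusted p of the clock list, 0.0071, was 0.0789 with slide as a block and 0.00633 to 0.111 without an array. These fits have fewer residual degrees of freedom, and the difference of Dbp was 1.40 with slide as a block and 1.21 to 1.46 without an array.

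Replicate numbers gave no sign of pairing: deviations from the group means of same-numbered arrays correlated at -0.165, -0.131 and 8.3e-04. Those of differently numbered arrays correlated at -0.102 to 0.157. With 3 arrays per group, whose deviations sum to 0, the check cannot exclude pairing. With the replicate block, 0 probes passed the adjusted threshold, 233 probes were at 2-fold, camera called 19 lists and the clock list had a mixed adjusted p of 0.139.

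Of 77 named genes, 66 kept their sign in every setting that held them and 11 did not. Cry2, at 5.6e-04, was -0.020 with quantile normalization, -0.029 with the median, -0.088 with normexp, -0.044 with normexp and quantile normalization, -0.052 with array weights, -0.088 with slide as a block and within slide 1, -0.093 with arthritis 1 and 3 against triptolide 1 and 3, -0.0017 with the muscle covariate and -0.070 to 0.057 without an array. Clock was 0.028 with normexp and quantile normalization. Il6 was -0.092 with normexp and -0.10 with array weights. With array weights Pvalb was 0.73, Tnnt3 1.12 and Actn3 2.18, and with arthritis 1 and 3 against triptolide 1 and 3 they were 0.86, 0.90 and 1.83. Without an array, Tnf ranged from -0.20 to 1.43, Il6 from -0.25 to 0.55, Mmp3 from -0.34 to 1.39, Mmp13 from -0.94 to 0.047, Ercc3 from -0.032 to 0.18, Tnnt3 from -3.21 to 0.53, Actn3 from -4.37 to 1.25 and Bhlhe40 from -0.093 to 0.29.

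Of the called lists, ribosomal proteins had a mean of 0.023 with quantile normalization, 0.050 with normexp and quantile normalization and 0.036 with slide as a block and within slide 1. Oxidative phosphorylation was at 0.047 with array weights and 0.099 with arthritis 1 and 3 against triptolide 1 and 3. Without an array, interferon-stimulated genes ranged from -0.072 to 0.88 and heat shock proteins from -0.41 to 0.066.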

Other observations

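The tests of slide, tissue makeup, array quality, oxidative phosphorylation, T and NK cells and triptolide 1 alone were chosen after the result was seen, as were the allowance for spread and the arrays left out in the test of clock output genes.

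Some further members stood out by their unadjusted values without passing over all probes. Cx3cl1, a membrane-bound chemokine gene, differed by 0.60 (SE 0.19) with triptolide and Irak3, an inhibitor of Toll-like receptor signalling, by 0.83 (SE 0.22), while being well above background on 1 arthritis array. The hypoxia-responsive genes Adm and Eno2 differed by 0.64 (SE 0.26) and 0.59 (SE 0.24), the semaphorin receptor gene Nrp2 by 0.86 (SE 0.30), the cytotoxic granule gene Gzma by 1.25 (SE 0.46) and Gap43, of growing axons, by -0.83 (SE 0.23). Without arthritis 2 Adm, Eno2 and Nrp2 were at 0.39, 0.34 and 0.54, and without triptolide 1 Gzma was at 0.77. The lists of glycolysis and hypoxia (camera adjusted p = 0.139) and angiogenic factors (0.220) were not called.

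For clock genes of opposed phase, which moved in opposite directions, tissue makeup of arthritis 2 is argued against, since without that array the mean signed difference of the tested members stayed at 95.9% of its size. A slide effect stays open: triptolide 1, which shares a slide with the arthritis arrays, deviated from them by 102% of the deviation of triptolide 2 and 3, which was above 90.5% of random lists and so short of the bound set. A shift in clock phase, whether by treatment or by the time of day of collection, which the labels do not give, may be a candidate explanation, but the prediction set for it before its genes were seen was not met. Of 5 clock output genes outside the list, 4 were tested and 1 was higher (Tspan4, 0.49), with a mean of -0.15 (SD 0.63 between genes), on the side set as counting against it. Its sign rests on Usp2 in arthritis 2: without that array the mean was 0.10 (SD 0.29) with 2 genes higher, above 83.5% of random lists, and without any other array it was -0.28 to -0.080, and the shift is left open only by the later allowance, as the mean of -0.15 lies within its spread of 0.

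Skeletal muscle genes far above the other arrays in arthritis 2 are consistent with muscle tissue in that sample, and the list's means of 1.20 and 1.02 in triptolide 1 and 3 against -3.49 and -3.51 in arthritis 1 and 3 leave open a smaller amount there. Of 8 tested muscle genes outside the list, set before their values were seen, 100% were highest there, by a median of 3.76 over the next array, and Tnnt3 stood at 8.61 there against 2.90 or less elsewhere. Poor array quality is argued against, since arthritis 2 was poorer than the other arrays on 0 of 3 measures (spike-in slope, share of spots above background and replicate spot CV). The oxidative phosphorylation call may rest on that array, as its mean difference without it was 2.66% of its size with all arrays. With arthritis 1 and 3 against triptolide 1 and 3, where triptolide had the higher muscle markers, the list was called upward (0.099, camera adjusted p = 2.7e-04). The muscle covariate (-0.23, camera adjusted p = 1.2e-14) cannot decide whether muscle is behind the call. The groups differed in the muscle mean by -0.19, so the correction could move little. Whether muscle is behind the call stays open. Beyond tissue makeup, no biological explanation was tested for this pattern.

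Interferon-stimulated genes were higher on average with triptolide. A single array may account for this: without triptolide 1 the mean difference was -17.1% of its size with all 6. For more T and NK cells the test could not decide, since their markers differed by 38.1% as much, between the bounds set. Array by array, those markers stood alike in triptolide 1 and 3 (0.52 and 0.50), whereas the interferon-stimulated genes stood at 1.19 and 0.15. The markers thus did not track the excess in triptolide 1, though both lists were lowest in triptolide 2 (-0.78 and -0.72). Triptolide treatment itself stays open, as untested.

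Among the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05, the real grouping gave 0 probes past the adjusted threshold and the highest other 1. As any count equals or exceeds 0, the 10 of 10 splits with as many say nothing about chance. The real grouping called 8 clock genes over the list alone and the highest other 0, with 1 split as large, the real grouping itself. The clock list was the 1 list that the mixed test called under the real grouping, so this comparison favoured that grouping from the start. It therefore says little about chance, and the most separated list of each other split was not compared. Each count of splits as large includes the real grouping. For 2-fold probes the real count was 225 and the highest other 600, with 4 splits as large. For camera lists these were 12 and 29, with 7 splits as large, and for fry mixed lists 1 and 1, with 4 as large. The split that put arthritis 1, arthritis 2 and triptolide 2 against the rest gave the 600 probes and the 29 lists. It was singled out after all 10 were seen, and what those arrays share was not tested.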
